A study of Mus musculus with 23 samples.

How the data were processed

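RNA was sequenced from tibialis anterior muscle, subcutaneous white fat and hypothalamus of mice given vehicle or oxaliplatin, with 1 library per sample and 23 samples over 3 tissues. Per the labels, RNA was taken with a magnetic bead kit, samples with an integrity number above 8 were used, muscle libraries were made with the Clontech SMARTer kit, and fat and hypothalamus libraries with a RiboErase kit, which depletes ribosomal RNA. The labels name STAR 2.5.1a (an aligner), Partek and DESeq2 as processing tools without saying what each did. The deposited tables hold expected counts per gene, that is, read counts estimated per gene and not scaled between libraries. Of the values, 45.7% in muscle, 41.4% in fat and 49.1% in hypothalamus were not whole numbers, and the column totals differed. The plan had assumed whole counts, so the expected counts were rounded to whole numbers first, and every later step used the rounded values. Every gene row summed to at least 10 over its table, so genes below that sum were removed before deposit. The genome build is not given in the sources used here. Gene start positions equalled those of GENCODE M21 (GRCm38) for 99.4% of shared identifiers in each table, and coordinates are given on that build, counted from 1. Genes were matched by symbol, and 34 rows in muscle, 51 in fat and 51 in hypothalamus carried joined identifiers.

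The tables held 20628 genes in muscle, 26702 in fat and 25623 in hypothalamus, and every column matched a sample. The number of total counts sets the counting precision, which is finest for abundant genes. The genes of 7SL, 7SK and RNase P RNA, abundant short non-coding RNAs, took 8.13% to 10.5% of counts in fat and 6.00% to 9.88% in hypothalamus. Mitochondrial transcripts took 12.2% to 23.2% of counts in muscle. No pair of libraries of 1 group was a copy or a resequencing of the other: over the 34 pairs, the lowest chi-square per degree of freedom was 7.37.

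Groups followed the titles. In muscle, the library titled oxaliplatin mouse 5 carries a vehicle treatment entry. It was placed with oxaliplatin, as its title, library name and the stated group sizes have it, and it was left out or set to vehicle as alternatives. Mouse numbers within a tissue name different animals in the arms, so they were not used as a block in the tests of the report.

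Each tissue was fitted on its own. Genes were kept by edgeR filterByExpr (minimum count 10, minimum total 15), which left 14737 in muscle, 19870 in fat and 18941 in hypothalamus. Library factors were TMM, and oxaliplatin was compared with vehicle by the edgeR quasi-likelihood F test with robust dispersion. The p values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were divided by the TMM factors, except those of Ttn, Acta1 and Ckm in fat. Library levels of lists are mean log2 CPM of the members with a prior count of 2, minus the vehicle mean. Differences in effect between tissues were tested in 1 edgeR fit over the libraries of both tissues, as the oxaliplatin effect in fat minus that in the other tissue. Overlap between muscle and fat was tested by the 1-sided Fisher's exact test per direction on genes tested in both.

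Gene lists of pathways and of cell types that the samples could hold were fixed before the data were examined and tested with limma camera on voom values at a preset correlation between genes of 0.01, for lists with at least 5 measured members, adjusted over the lists of a tissue. Camera asks whether the members rank higher or lower than all other genes. It was repeated with a correlation estimated from the data, and with fry, which tests whether the members move, on balance, in 1 direction and does not compare them with other genes. Members were also adjusted over the list alone. Lists share some genes, such as Btg2 (p53 targets and immediate early genes), Insig1 (lipogenesis and cholesterol synthesis) and Cdkn1a (p53 targets and, in muscle, denervation).

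The rule for named genes was set before the data were examined. Per tissue it took the 10 largest rises and 10 largest falls among called genes with a group mean of at least 1 CPM and no overlap between the arms. Where fewer than 5 such genes were found, it took the 5 of smallest p in each direction, with values only. It also took up to 4 members of each list by smallest adjusted p, genes chosen in advance for each tissue, and the 5 largest differences in each direction between tissues. Unnamed gene models were left out. The text names a part of the list members.

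The alternatives planned were DESeq2 size factors and upper quartile factors in edgeR, DESeq2, limma-voom with and without quality weights, no filter, a filter at a mean of 1 CPM, an absolute log2 fold change of at least 1, 1 fit over all tissues, the mouse number as a block, the animal as a random effect, each library left out in turn, and both readings of the muscle mouse 5 label. Added after seeing the data were fat without vehicle mouse 4 and oxaliplatin mouse 5, the myofibre level as a covariate in fat, the adipocyte level as a covariate in muscle, and the overlap without mouse 5. How the libraries group by chance was tested with other splits of the same libraries.

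The tests were tried on simulated counts with the means and spread of each tissue, in which 100 genes were changed 2-fold and 100 others 4-fold. In muscle 53% and 83% were recovered, with 13 false calls among 14507 unchanged genes. In fat 7% and 70% were recovered, with 5 false calls among 19640, and in hypothalamus 65% and 85%, with 19 among 18711. For the difference between fat and muscle the shares were 6% and 47%, and between fat and hypothalamus 6% and 49%, each with 1 false call. In each tissue the 1 raised list was found, and 0 of 20 unchanged lists were called. The simulated genes were drawn independently and the lists at random, so this trial cannot show false calls of lists with correlated members. Nor can it show false gene calls that come from structure shared by many genes across the real libraries. In the data the estimated correlation was, for example, 0.947 for oxidative phosphorylation genes in muscle. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.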

Results

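Gene expression was measured by RNA sequencing in 3 tissues of C57BL/6 mice, an inbred laboratory strain, after 8 weeks of vehicle or of oxaliplatin at 10 mg/kg. Oxaliplatin is a platinum drug that forms DNA crosslinks and is given against colorectal cancer. The tissues were tibialis anterior, a fast-twitch muscle of the shin, subcutaneous white fat, and hypothalamus, the brain region that controls feeding and energy balance. Of the 23 libraries, 9 came from muscle (5 oxaliplatin, 4 vehicle), 7 from fat (4 oxaliplatin, 3 vehicle) and 7 from hypothalamus (4 oxaliplatin, 3 vehicle). Total counts, in mega counts (M), were 22.4 to 32.2 M per oxaliplatin muscle library and 27.3 to 31.2 M per vehicle muscle library. In fat they were 16.5 to 18.0 M with oxaliplatin and 16.9 to 22.7 M with vehicle. In hypothalamus they were 23.6 to 26.4 M with oxaliplatin and 27.3 to 28.5 M with vehicle, so there every oxaliplatin library was shallower than every vehicle library. The muscle library titled oxaliplatin mouse 5 has vehicle as its treatment entry, while its title, its library name and the stated group sizes place it with oxaliplatin. It was counted as oxaliplatin, and the values under the other reading are given with the muscle results. Levels are normalised counts per M (CPM), as mean ± SD over the libraries of a group, and changes are log2 fold changes of oxaliplatin over vehicle ± SE.

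The muscle comparison addressed the transcripts that oxaliplatin changed in tibialis anterior. Pfkfb3, whose product makes the glycolysis activator fructose 2,6-bisphosphate, rose 3.18-fold, from 60.6 ± 10.3 CPM in 4 vehicle mice to 192 ± 25.3 CPM in 5 oxaliplatin mice (log2 fold change 1.67 ± 0.15, edgeR adjusted p = 0.00106). Pnmt, the enzyme that makes adrenaline from noradrenaline, rose from 0.504 ± 0.163 to 4.98 ± 1.64 CPM (3.31 ± 0.31, adjusted p = 0.00106). Acer2, a ceramidase of the Golgi, rose from 2.93 ± 0.748 to 14.8 ± 5.49 CPM (2.33 ± 0.29, adjusted p = 0.0127). Amd1, the S-adenosylmethionine decarboxylase of polyamine synthesis, fell from 476 ± 136 to 149 ± 54.3 CPM (-1.68 ± 0.28, adjusted p = 0.0486). In each of these genes all 5 oxaliplatin libraries lay on 1 side of all 4 vehicle libraries.

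Genes of leukocyte recruitment and of vessels were among the others that rose in muscle. Ccl2, a chemokine that draws monocytes, rose from 0.435 to 2.23 CPM (2.31 ± 0.33, adjusted p = 0.0211), and Icam1, an adhesion molecule for leukocytes on endothelium, from 2.81 to 8.62 CPM (1.61 ± 0.25, adjusted p = 0.0407). Angpt2, an endothelial ligand of the Tie2 receptor, rose by 1.30 ± 0.20 (adjusted p = 0.0278), and Higd1b, a gene expressed in pericytes, by 1.52 ± 0.19 (adjusted p = 0.0127). Nr1d1, a repressor in the circadian clock, rose from 81.0 to 209 CPM (1.37 ± 0.19, adjusted p = 0.0211). Car14, a membrane carbonic anhydrase, rose by 1.15 ± 0.17 (adjusted p = 0.0278), and Hectd2os, an antisense transcript, by 1.60 ± 0.27 (adjusted p = 0.0486). Besides Amd1, the genes that fell were Pthlh, the parathyroid hormone-like hormone (-1.60 ± 0.28, adjusted p = 0.0486), Lonrf1 (-1.16 ± 0.20, adjusted p = 0.0488), the Mediator kinase Cdk19 (-1.10 ± 0.19, adjusted p = 0.0443), the membrane progestin receptor Paqr7 (-1.09 ± 0.18, adjusted p = 0.0443), Smtnl2 (-1.08 ± 0.14, adjusted p = 0.0127) and Acat2, a cytosolic acetyl-CoA acetyltransferase (-0.72 ± 0.12, adjusted p = 0.0486). On GRCm38, Pfkfb3 (ENSMUSG00000026773) lies on chromosome 2 from 11471433 to 11554077, minus strand, and Pnmt (ENSMUSG00000038216) on chromosome 11 from 98386450 to 98388181, plus strand.

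In total 24 of 14737 tested muscle genes passed at an adjusted p under 0.05, 17 higher and 7 lower, and the arms did not overlap in any of the 24. Over all tested genes the arms were apart in 573, which is 3.89% against the 1.59% that chance gives. The count was 14, 17, 3 and 16 without vehicle mice 1 to 4, and it was 2, 8, 11, 5 and 8 without oxaliplatin mice 1, 2, 3, 4 and 5 in turn. Pnmt and Pfkfb3 kept their call without any 1 of the 9 libraries, while the other 16 called genes followed through these fits, Pecam1 among them, each lost it without at least 1, with a highest adjusted p of 0.0507 for Smtnl2 and 0.189 for Pthlh. None of the 18 changed sign in any setting. With 1 library left out the log2 change was -1.17 to -0.93 for Smtnl2, -1.81 to -1.39 for Pthlh and 0.62 to 0.74 for Pecam1. With mouse 5 set to vehicle, edgeR called 0 genes, with 701 at an unadjusted p under 0.05, against 1414 with mouse 5 as oxaliplatin. The p53 target genes of this library lay 0.763 (log2) above the vehicle mean, against 0.0955 in the highest vehicle library. As weighed below, this argues against the vehicle reading. With mouse 5 as oxaliplatin, DESeq2 called 254 genes, 161 of them higher, and limma-voom called 13.

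Genes chosen in advance for muscle wasting and drug stress varied between mice. Cdkn1a, the p53-induced cell cycle inhibitor p21, was 6.79 ± 1.97 CPM with vehicle and 64.6 ± 41.5 CPM with oxaliplatin, 33.0 to 125 CPM per library against 5.13 to 9.64 (3.25 ± 0.49, adjusted p = 0.0526 over all genes). It lies on chromosome 17 from 29090976 to 29100727, plus strand (ENSMUSG00000023067). Of the 12 such genes tested, Cdkn1a was the only 1 that passed when adjusted over the list alone. The muscle ubiquitin ligase Fbxo32 (atrogin-1) averaged 214 ± 35.2 and 356 ± 275 CPM (0.73 ± 0.51, adjusted p = 0.746), with 762 CPM in oxaliplatin mouse 1, 519 in mouse 5 and 131 to 194 in the other oxaliplatin mice. Trim63 (MuRF1), the other classic atrophy ligase, averaged 187 and 260 CPM (0.48 ± 0.27, adjusted p = 0.642). The metal-binding metallothionein genes Mt1 and Mt2 gave 1.74 ± 0.61 (adjusted p = 0.400) and 2.02 ± 1.01. The log2 changes of the remaining genes were 0.32 for Mdm2, 0.56 for Pdk4, 0.18 for Mstn, 0.59 for Foxo1, 0.45 for Klf15, 0.06 for Ppargc1a and -0.41 for Igf1. Il6 and Gdf15 were below the count filter, with Gdf15 at 0.0811 CPM with vehicle and 0.572 CPM with oxaliplatin.

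Of 29 gene lists fixed before the data were examined, 14 passed the camera test in muscle, 10 higher and 4 lower. None kept its call with a correlation between genes estimated from the data, where the smallest adjusted p was 0.300, and fry called 0 lists. The p53 targets rose as a list (26 tested, 6 higher when adjusted over the list alone, median 0.33, adjusted p = 1.7e-06, and adjusted p = 0.543 with an estimated correlation). Its members of smallest p were Cdkn1a, the antiproliferative gene Btg2 (0.90 ± 0.21), the death effector Bax (0.69 ± 0.16) and the stress sensor Sesn1 (1.36 ± 0.36). Glucocorticoid-responsive genes, those that corticosteroid hormones induce, rose (23 tested, 2 higher and 1 lower over the list alone, median 0.54, adjusted p = 7.48e-06, and adjusted p = 0.788 with an estimated correlation). Fkbp5, a chaperone of the glucocorticoid receptor, went from 11.7 to 45.1 CPM (1.94 ± 0.50), and the phosphatase gene Dusp1 went the other way (-0.88 ± 0.26). The list level per oxaliplatin library, against the vehicle mean, was 0.66, -0.10, 0.21, 0.30 and 1.42 for mice 1 to 5, and -0.44 to 0.28 in vehicle. Immediate early genes, the fast transcriptional response to stimulation, rose (20 tested, 3 higher and 1 lower over the list alone, median 0.48, adjusted p = 0.00108, and adjusted p = 0.300 with an estimated correlation), with Egr1 at 1.01 ± 0.19 and Ier3 at 0.63 ± 0.12. These 3 lists passed without each of the 9 libraries in turn, but the glucocorticoid median was 0.28 without oxaliplatin mouse 5, and with mouse 5 set to vehicle it was -0.06 (adjusted p = 0.923).

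Endothelial markers rose in muscle (17 tested, Pecam1 called over all genes, 4 over the list alone, median 0.26, adjusted p = 1.36e-06, and adjusted p = 0.300 with an estimated correlation). Pecam1, an adhesion protein of endothelial junctions, rose from 47.4 to 75.8 CPM (0.68 ± 0.11, adjusted p = 0.0443), and the vessel genes Eng and Vwf gave 0.50 ± 0.11 and 0.92 ± 0.22. Extracellular matrix genes fell (34 tested, 0 over the list alone, 31 below 0, median -0.76, adjusted p = 1.18e-08, and adjusted p = 0.788 with an estimated correlation). Among them Col6a2, a collagen VI chain, was 14.1 CPM with vehicle and 5.55 with oxaliplatin (-1.36 ± 0.44), and the matrix protease Mmp2 was 40.9 and 22.4 CPM (-0.87 ± 0.33). The matrix level was -0.73 and -0.51 in vehicle mice 1 and 2 and 0.41 and 0.84 in vehicle mice 3 and 4, which were also the vehicle libraries high in adipocyte markers (1.04 and 1.71, against -1.43 and -1.32) and macrophage markers (0.40 and 1.19, against -1.02 and -0.57). Both the endothelial and the matrix list passed without each of the 9 libraries in turn, with a matrix median of -0.43 without vehicle mouse 4.

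A further 9 lists passed in muscle, and the median and adjusted p without a library follow it in brackets where the call was lost. Cytosolic ribosomal proteins rose (38 tested, all 38 above 0, 0 over the list alone, median 0.19, adjusted p = 1.4e-05, and adjusted p = 0.795 with an estimated correlation), Rpsa for instance at 0.35 ± 0.18. The call was lost without vehicle mouse 4 (0.03, 0.677). The atrophy genes, which rise in wasting muscle, rose (28 tested, 0 over the list alone, median 0.19, adjusted p = 0.0133, and adjusted p = 0.795 with an estimated correlation), Foxo3 and Bnip3 for instance at 0.63 ± 0.22 and 0.55 ± 0.22. This call was lost without vehicle mouse 4 (0.14, 0.0624) or oxaliplatin mice 1 (0.12, 0.280) or 5 (0.18, 0.0895). Proteasome subunits rose (31 tested, 0 over the list alone, median 0.10, adjusted p = 0.0116, and adjusted p = 0.795 with an estimated correlation), Psmb3 at 0.33 ± 0.14, and lost it without vehicle mouse 4 (0.04, 0.786) or oxaliplatin mouse 1 (0.03, 0.313). Denervation-responsive genes rose (19 tested, Cdkn1a over the list alone, median 0.24, adjusted p = 0.0208, and adjusted p = 0.788 with an estimated correlation), with the acetylcholine receptor subunit Chrna1 at 0.63 ± 0.23. The call was lost without vehicle mouse 2 (0.24, 0.230) or oxaliplatin mouse 5 (0.18, 0.121). Inflammatory genes rose (20 tested, 4 over the list alone, adjusted p = 0.0264, and adjusted p = 0.795 with an estimated correlation) with 10 members on each side of 0 and a median of 0.05. Ccl2 and Icam1 were called over all genes, and the list lost its call without vehicle mice 1 (-0.02, 0.234) or 2 (-0.08, 0.295) or oxaliplatin mice 1 (-0.11, 0.0519) or 5 (-0.01, 0.0516).

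Schwann cell and nerve markers rose (14 tested, 0 over the list alone, median 0.32, adjusted p = 0.0400, and adjusted p = 0.795 with an estimated correlation), with the myelin gene Mbp at 0.50 ± 0.21. This call was lost without vehicle mice 2 (0.27, 0.219) or 3 (0.22, 0.194) or oxaliplatin mice 2 (0.19, 0.213) or 5 (0.18, 0.222). Targets of NRF2, the regulator of antioxidant genes, fell (23 tested, 1 higher and 2 lower over the list alone, median -0.16, adjusted p = 0.0218, and adjusted p = 0.788 with an estimated correlation). The quinone reductase Nqo1 gave -0.69 ± 0.14 and the epoxide hydrolase Ephx1 0.68 ± 0.13, and the call was lost without vehicle mouse 4 (-0.15, 0.107) or oxaliplatin mice 3 (-0.14, 0.0845) or 5 (-0.12, 0.0628). Macrophage markers fell (20 tested, 2 over the list alone, median -0.40, adjusted p = 0.0116, and adjusted p = 0.795 with an estimated correlation), among them the antigen-presenting genes H2-Aa (-2.11 ± 0.55) and H2-Ab1 (-2.20 ± 0.58). Without vehicle mouse 4 their median was 0.11 (0.978), and the call was also lost without vehicle mouse 3 (-0.37, 0.0840) or oxaliplatin mouse 3 (-0.25, 0.0729). Fibroblast markers fell (16 tested, Ly6a higher over the list alone, median -0.49, adjusted p = 0.00465, and adjusted p = 0.795 with an estimated correlation). The call was lost without vehicle mouse 4 (-0.16, 0.455).

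The other 15 muscle lists did not pass. Clock genes had a median of -0.08 and a mean of 0.19 (adjusted p = 0.493), with Nr1d1 called and 4 members higher and 1 lower over the list alone. Autophagy genes had a median of 0.04 (adjusted p = 0.141), with the FOXO-responsive gene Depp1 at 2.49 ± 0.57, and cell cycle genes -0.13 (0.154). The medians were 0.11 for interferon-stimulated genes (0.215), -0.21 for mitochondrially encoded genes (0.232), 0.06 for fatty acid oxidation (0.252), -0.15 for satellite cell markers (0.350), -0.07 for fast fibre genes (0.759) and -0.02 for the unfolded protein response (0.740). In 6 further lists the median, the mean and the direction of the test differed in sign. These were the integrated stress response (0.08, -0.03, test upward, adjusted p = 0.893), oxidative phosphorylation (-0.02, -0.04, upward, 0.835), erythroid markers (0.30, 0.13, downward, 0.371), glycolysis (-0.03, 0.01, downward, 0.830), slow fibre genes (-0.23, -0.10, upward, 0.740) and adipocyte markers (-0.35, -0.46, upward, 0.343), as they also did in the clock list. For the muscle list: nuclear-encoded oxidative phosphorylation, the median was -0.21 without vehicle mouse 4 (adjusted p = 0.00226), but 0.13 and 0.14 without vehicle mice 1 and 2 (adjusted p = 0.0118 and 0.00821).

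**Figure D1:**
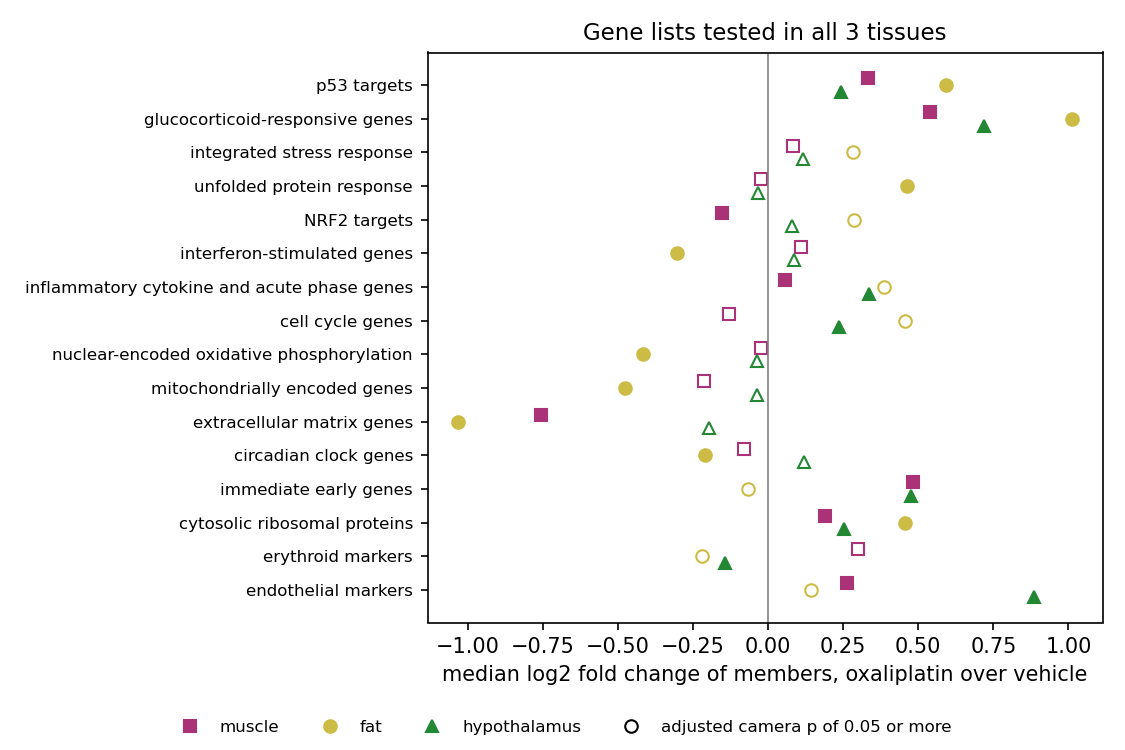
Median log2 fold change (oxaliplatin over vehicle) of the members of the 16 gene lists tested in all 3 tissues, with muscle as squares, fat as circles and hypothalamus as triangles, and open symbols where the adjusted camera p was 0.05 or more. Glucocorticoid-responsive genes lie at 0.54, 1.01 and 0.72 in muscle, fat and hypothalamus, and p53 targets at 0.33, 0.59 and 0.24.

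The fat comparison addressed the same question in subcutaneous white fat. Lep, which encodes the satiety hormone leptin, was 898 ± 20.3 CPM in 3 vehicle mice and 105 ± 192 CPM in 4 oxaliplatin mice (-3.10 ± 1.49, adjusted p = 0.230). It was 5.16 to 11.7 CPM in oxaliplatin mice 2 to 4 and 394 CPM in mouse 5. Scd1, which desaturates fatty acids, was 39732 CPM with vehicle, 433 to 938 CPM in oxaliplatin mice 2 to 4 and 12993 CPM in mouse 5 (-3.42 ± 1.32, adjusted p = 0.166). Lists of lipogenesis, adipocyte identity and oxidative phosphorylation genes fell, while glucocorticoid-responsive genes, p53 targets and ribosomal protein genes rose. With an estimated correlation none of these lists passed, with adjusted p = 0.127 for p53 targets and adjusted p = 0.510 for the other 5. No single gene passed over all 19870 tested.

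The fat genes of smallest p all had an adjusted p of 0.0751, and their values are given as measured. Gramd1b, which carries cholesterol from the plasma membrane, was 36.6 ± 4.55 CPM with vehicle and 95.5 ± 11.8 CPM with oxaliplatin (1.38 ± 0.15). Il4ra, the interleukin 4 receptor, was 47.6 and 122 CPM (1.36 ± 0.16), and the uridine phosphorylase Upp1, Clca3a1 and the small nucleolar RNA Snord22 gave 2.37 ± 0.28, 2.86 ± 0.35 and 1.31 ± 0.16. On the lower side, Sfrp5, a secreted Wnt inhibitor made by adipocytes, was 112 ± 29.0 and 22.1 ± 3.73 CPM (-2.34 ± 0.22), and Fgf1, a growth factor, 30.4 ± 2.12 and 7.65 ± 1.68 CPM (-1.99 ± 0.18). Bhlhe41, a clock repressor, was 106 and 15.9 CPM (-2.74 ± 0.31), Ccdc9b gave -1.38 ± 0.14, and Unc79, a subunit of the NALCN sodium channel complex, -3.29 ± 0.36. In each of these 10 genes the 4 oxaliplatin libraries, mouse 5 included, lay apart from the 3 vehicle libraries. Gramd1b (ENSMUSG00000040111) lies on chromosome 9 from 40293233 to 40531383, minus strand, and Lep (ENSMUSG00000059201) on chromosome 6 from 29060220 to 29073877, plus strand.

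edgeR called 0 fat genes at an adjusted p under 0.05, with 5178 at an unadjusted p under 0.05, 2664 higher and 2514 lower. limma-voom also called 0, while DESeq2 called 2450 (1168 higher, 1282 lower) and limma-voom with library quality weights 5083. The arms did not overlap in 4274 genes, 21.5% against the 5.71% that chance gives. Without oxaliplatin mouse 5 edgeR called 4969 genes, 2346 higher and 2623 lower, and without oxaliplatin mouse 2 it called 6. Vehicle mouse 4 stood apart in muscle fibre transcripts, with Ttn (titin) at 51767 CPM, Acta1 (skeletal actin) at 6686 and Ckm (muscle creatine kinase) at 5086. Ttn was 796 CPM in vehicle mouse 1, 7.53 in vehicle mouse 2 and 251 to 2577 in the oxaliplatin mice. The CPM of these 3 genes were not divided by the TMM factors. Without both vehicle mouse 4 and oxaliplatin mouse 5, a setting chosen after seeing the data, 4087 genes were called, 1743 higher and 2344 lower.

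**Figure D2:**
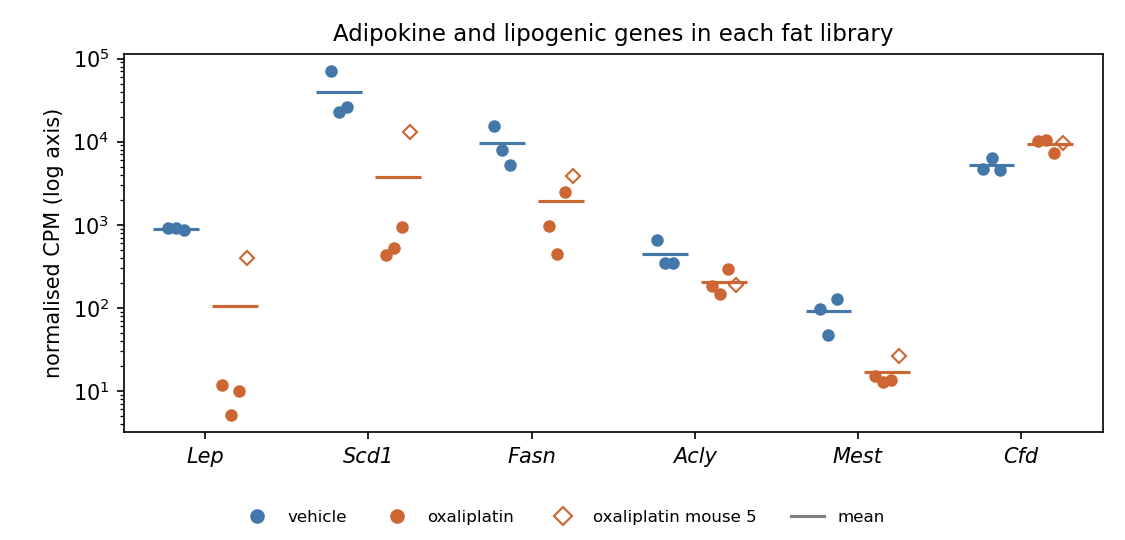
Normalised CPM per fat library, on a log axis, of Lep, Scd1, Fasn, Acly, Mest and Cfd in 3 vehicle and 4 oxaliplatin mice, with bars at the group means and an open diamond for oxaliplatin mouse 5. Mouse 5 lies at 394 CPM for Lep, between the other oxaliplatin mice (5.16 to 11.7 CPM) and the vehicle mean of 898 CPM.

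Of the fat genes chosen in advance, Cdkn1a was 13.2 ± 3.78 CPM with vehicle and 164 ± 77.6 CPM with oxaliplatin (3.63 ± 0.47, adjusted p = 0.0751), with 76.4 CPM in mouse 5, and it was the only 1 of 15 tested that passed when adjusted over the list alone. Fatty acid synthase Fasn was 9568 and 1928 CPM (-2.31 ± 0.74, adjusted p = 0.133), the ATP citrate lyase Acly 448 and 202 CPM (-1.15 ± 0.32, adjusted p = 0.120), and Srebf1, the transcription factor of lipid synthesis, 568 and 288 CPM (-0.98 ± 0.37, adjusted p = 0.162). The lipase genes Lipe and Pnpla2 gave -0.94 ± 0.30 and 0.50 ± 0.34. Adipoq, the hormone adiponectin, was 1116 and 877 CPM (-0.35 ± 0.25), and Pparg, the master regulator of adipocytes, gave 0.39 ± 0.23. The log2 changes were -0.69 for Acaca, 0.80 for Mlxipl, -0.26 for Ppargc1a, -0.42 for Ccl2 and -0.11 for Slc2a4. Ucp1, the uncoupling protein of brown and beige fat, and Il6 were below the count filter, with Ucp1 at 3.72 CPM with vehicle and 0.0545 CPM with oxaliplatin.

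Of 28 lists, 17 passed camera in fat, 5 higher and 12 lower. None kept its call with an estimated correlation, where the smallest adjusted p was 0.127, and fry called 3, the p53 targets, the unfolded protein response and cholesterol synthesis. Glucocorticoid-responsive genes rose (23 tested, all above 0, 9 over the list alone, median 1.01, adjusted p = 8.19e-07, and adjusted p = 0.510 with an estimated correlation). Fkbp5 was 97.3 and 684 CPM (2.81 ± 0.71), and Klf15, a metabolic transcription factor, 76.5 and 181 CPM (1.24 ± 0.30). The list level was 2.01, 1.63 and 1.01 in oxaliplatin mice 2, 3 and 4 and 0.16 in mouse 5. The p53 targets rose (30 tested, 13 higher and 2 lower over the list alone, median 0.59, adjusted p = 0.00097, and adjusted p = 0.127 with an estimated correlation). Beside Cdkn1a, the stress hormone Gdf15 was 0.647 and 5.20 CPM (2.99 ± 0.42) and Trp53inp1, a p53 cofactor, 31.3 and 424 CPM (3.76 ± 0.77), and the level in mouse 5 was 0.51, against 0.54 to 0.66 in the other oxaliplatin mice. Ribosomal protein genes rose (38 tested, all above 0, 25 over the list alone, median 0.46, adjusted p = 1.02e-13, and adjusted p = 0.510 with an estimated correlation), with Rpl32 at 0.68 ± 0.16. Genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, rose (20 tested, 7 over the list alone, median 0.46, adjusted p = 0.000282, and adjusted p = 0.510 with an estimated correlation), with Manf at 0.72 ± 0.13 and Creld2 at 0.90 ± 0.17. These 4 lists passed without each of the 7 libraries in turn.

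Lipid and energy genes fell in fat. Lipogenesis genes fell (27 tested, 9 lower and 1 higher over the list alone, median -0.93, adjusted p = 0.00372, and adjusted p = 0.510 with an estimated correlation), with the desaturase Scd2 at 527 and 176 CPM (-1.58 ± 0.24) and the malic enzyme Me1 at 438 and 143 CPM (-1.62 ± 0.33). Cholesterol synthesis genes fell (24 tested, 9 lower and 1 higher over the list alone, median -0.53, adjusted p = 0.000378, and adjusted p = 0.127 with an estimated correlation), with Hsd17b7 at -1.03 ± 0.17. Adipocyte identity genes and adipokines fell (24 tested, Mest over the list alone, median -0.92, adjusted p = 0.000478, and adjusted p = 0.510 with an estimated correlation). Mest, an imprinted gene linked to adipocyte size, was 90.5 and 17.0 CPM (-2.41 ± 0.39), while Cfd, the secreted protease adipsin, gave 0.87 ± 0.25. Their level was -1.87, -1.86 and -1.61 in oxaliplatin mice 2, 3 and 4 and -0.22 in mouse 5. Nuclear-encoded oxidative phosphorylation genes fell (45 tested, 26 over the list alone, 43 below 0, median -0.42, adjusted p = 1.53e-11, and adjusted p = 0.510 with an estimated correlation), with Ndufb8 of complex I at 95.0 and 53.1 CPM (-0.84 ± 0.16). The myofibre level moved with this list, at 6.16 in vehicle mouse 4 and -5.67 in vehicle mouse 2, and without mouse 4 the oxidative phosphorylation median was -0.33. These 4 lists passed without each of the 7 libraries in turn.

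Matrix and stromal genes fell in fat as well. Extracellular matrix genes fell (35 tested, 0 over the list alone, median -1.03, adjusted p = 0.00122, and adjusted p = 0.679 with an estimated correlation), with Dpt, a matrix protein of the dermis, at 565 and 121 CPM (-2.23 ± 1.09). Fibroblast markers fell (17 tested, 0 over the list alone, median -1.09, adjusted p = 0.000208, and adjusted p = 0.527 with an estimated correlation), with Smoc2 at -1.89 ± 0.62. The 2 lists share 5 genes in the plan. The matrix level was -2.26, -1.58 and -1.71 in oxaliplatin mice 2, 3 and 4 and 0.29 in mouse 5. Both lists passed without each library in turn, and without mouse 5 the medians were -2.03 for matrix genes and -1.79 for fibroblast markers.

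In 7 further fat lists the call, though not always the size of the shift, depended on single libraries, and the median and adjusted p without a library follow it in brackets. Fatty acid oxidation fell (28 tested, 0 over the list alone, median -0.32, adjusted p = 0.00318, and adjusted p = 0.527 with an estimated correlation), with the mitochondrial carrier Ucp3 at -1.72 ± 0.42. This call was lost without vehicle mouse 1 (-0.15, 0.0857). Lipolysis genes fell (23 tested, Adrb1 over the list alone, median -0.43, adjusted p = 0.0233, and adjusted p = 0.510 with an estimated correlation), with the beta-1 adrenergic receptor Adrb1 at 20.9 and 1.95 CPM (-3.42 ± 0.69). The call was lost without vehicle mouse 1 (-0.40, 0.119). Thermogenic genes fell (24 tested, 0 over the list alone, median -0.31, adjusted p = 0.0481, and adjusted p = 0.510 with an estimated correlation), with Cox7a1 at -4.95 ± 1.07 and Elovl3, a fatty acid elongase, at 4.49 ± 1.27. Cox7a1 is also a muscle fibre gene, and it was highest in vehicle mouse 4 (25.8 CPM), the library rich in myofibre markers. The call was lost without that mouse (-0.11, 0.0973), without vehicle mouse 1 (-0.38, 0.0857) or without oxaliplatin mouse 5 (-0.29, 0.369). Mitochondrially encoded genes fell (13 tested, 0 over the list alone, median -0.48, adjusted p = 0.0282, and adjusted p = 0.770 with an estimated correlation), with mt-Nd2 at -0.64 ± 0.31. This call was lost without vehicle mice 1 (-0.34, 0.239) or 4 (-0.31, 0.197) or oxaliplatin mice 3 (-0.41, 0.0571), 4 (-0.35, 0.104) or 5 (-0.44, 0.126). Clock genes passed in the lower direction (19 tested, 9 lower and 4 higher over the list alone, median -0.21, adjusted p = 0.0282, and adjusted p = 0.510 with an estimated correlation), with the activator Arntl at 2.82 and its repressors Ciart and Nr1d2 at -1.41 ± 0.18 and -0.88 ± 0.14, and lost the call without vehicle mouse 1 (-0.51, 0.0667) or oxaliplatin mouse 5 (-0.10, 0.355). Interferon-stimulated genes fell (25 tested, 0 over the list alone, median -0.30, adjusted p = 0.0172, and adjusted p = 0.770 with an estimated correlation), with the antiviral gene Ifit3 at -1.12 ± 0.48, and lost the call without vehicle mouse 2 (-0.23, 0.0743) or oxaliplatin mouse 3 (-0.08, 0.207), with a median of -0.72 without oxaliplatin mouse 5. Lymph node and B cell markers rose (17 tested, 0 over the list alone, median 2.89, adjusted p = 0.0233, and adjusted p = 0.770 with an estimated correlation), with the B cell chemokine Cxcl13 at 5.07 and 84.8 CPM (4.05 ± 1.15). Their level was -1.12 in oxaliplatin mouse 2 and 2.31 and 4.01 in mice 4 and 5, and the call was lost without vehicle mouse 4 (2.67, 0.0520) or oxaliplatin mouse 5 (1.80, 0.126).

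The other 11 fat lists did not pass. T and NK cell markers had a median of 2.05 (adjusted p = 0.0766), with Cd3e at 2.62 ± 0.41 and levels of -1.20 in oxaliplatin mouse 2 and 1.03 to 2.40 in mice 3 to 5. Skeletal myofibre markers had a median of -5.12 (0.504), which was 1.36 without vehicle mouse 4 (adjusted p = 0.00260). Mammary and skin epithelial markers had a median of -3.31 (0.504), with 1 of 8 members higher and 5 lower over the list alone, the keratin Krt14 at -5.38 ± 1.82, and levels of 1.11 and 1.31 in vehicle mice 1 and 2, -2.42 in vehicle mouse 4 and 0.20 in oxaliplatin mouse 4. The medians were -0.12 for macrophage markers (0.504), 0.14 for endothelial markers (0.278), 0.28 for the integrated stress response (0.191), 0.29 for NRF2 targets (0.236), 0.38 for inflammatory genes (0.342) and 0.46 for cell cycle genes (0.504). Erythroid markers had a median of -0.22 and a mean of 0.20 (test downward, adjusted p = 0.234), and immediate early genes a median of -0.07 and a mean of 0.33 (test upward, adjusted p = 0.694).

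The hypothalamus comparison addressed the transcripts that changed in the brain region that controls appetite. Vwf, the von Willebrand factor of endothelium and platelets, rose from 30.0 ± 3.37 CPM in 3 vehicle mice to 236 ± 77.0 CPM in 4 oxaliplatin mice (2.97 ± 0.30, edgeR adjusted p = 0.0193). Lcn2, an acute phase iron-binding protein, rose from 0.155 ± 0.146 to 6.33 ± 3.85 CPM (5.31 ± 0.71, adjusted p = 0.0458), and Lrg1, a secreted glycoprotein of inflamed vessels, from 0.608 ± 0.315 to 5.29 ± 0.608 CPM (3.11 ± 0.31, adjusted p = 0.00738). The ceramidase gene Acer2, which also rose in muscle, went from 6.11 ± 1.55 to 44.8 ± 10.1 CPM (2.87 ± 0.23, adjusted p = 0.00738). Npy and Agrp, the hunger peptides of the arcuate nucleus, were 13.1 and 77.5 CPM, and 2.42 and 11.4 CPM, but neither passed over all genes.

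Cebpd, a transcription factor of the acute phase, rose from 4.08 to 23.8 CPM (2.55 ± 0.34, adjusted p = 0.0483). The endothelial surface proteins Adgrl4, Ly6a and Clec14a rose by 1.76 ± 0.19, 1.75 ± 0.22 and 1.63 ± 0.22 (adjusted p = 0.0136, 0.0297 and 0.0297). B3gnt3, a glycosyltransferase of lymph node vessels, rose by 2.12 ± 0.30 (adjusted p = 0.0331) and Tmem252 by 1.72 ± 0.24 (adjusted p = 0.0297). Outside the rule for named genes, and chosen after their values were seen, Vegfa, the main endothelial growth factor, rose from 35.1 to 86.0 CPM (1.29 ± 0.13, adjusted p = 0.00738) and Slc2a1, the glucose transporter of the blood-brain barrier, from 124 to 299 CPM (1.27 ± 0.18, adjusted p = 0.0425). Vwf (ENSMUSG00000001930) lies on chromosome 6 from 125546774 to 125686679, plus strand, and Agrp (ENSMUSG00000005705) on chromosome 8 from 105566698 to 105637393, minus strand.

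In total 28 of 18941 tested hypothalamus genes passed, all 28 higher, and the arms did not overlap in any of them. Over all tested genes the arms were apart in 1880, 9.93% against the 5.71% that chance gives. The count was 1 without vehicle mouse 1, 1 without vehicle mouse 2 and 0 without vehicle mouse 4, where 1152 genes had an unadjusted p under 0.05 in edgeR. It was 31 without oxaliplatin mouse 2, 25 of them among the 28. It was 6 without oxaliplatin mouse 3, 2 without mouse 4 and 655 without mouse 5 (399 higher, 256 lower). Each of the 15 called genes followed through these fits lost its call without at least 1 library, Acer2 without vehicle mouse 2 or 4 (highest adjusted p = 0.0941). The sizes moved less than the calls, and none of the 15 changed sign in any setting. With 1 library left out the log2 change was 2.80 to 3.17 for Vwf, 2.74 to 3.09 for Acer2, 1.14 to 1.30 for Eng and 4.83 to 6.38 for Lcn2. Over all libraries DESeq2 called 262 genes, 217 of them higher, and limma-voom 11.

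**Figure D3:**
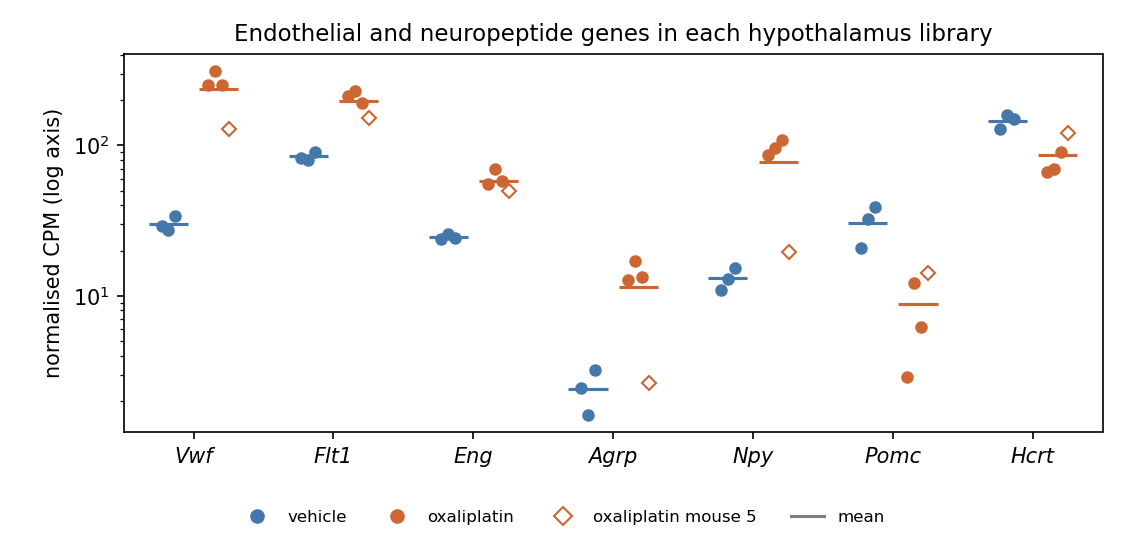
Normalised CPM per hypothalamus library, on a log axis, of Vwf, Flt1, Eng, Agrp, Npy, Pomc and Hcrt in 3 vehicle and 4 oxaliplatin mice, with bars at the group means and an open diamond for oxaliplatin mouse 5. Mouse 5 lies at 128 CPM for Vwf, above all vehicle mice (27.3 to 33.8 CPM), and at 2.63 CPM for Agrp, within the vehicle range of 1.62 to 3.21 CPM.

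Among 15 hypothalamus genes chosen in advance, 3 were higher and 4 lower when adjusted over the list alone, and none passed over all genes in edgeR. Npy gave 2.57 ± 0.59 (adjusted p = 0.308), with 86.4 to 108 CPM in oxaliplatin mice 2 to 4 and 19.6 CPM in mouse 5. Agrp gave 2.24 ± 0.61 (adjusted p = 0.348), with 12.8 to 17.0 CPM in oxaliplatin mice 2 to 4 and 2.63 CPM in mouse 5. Pomc, the precursor of the satiety peptide alpha-MSH, was 30.6 ± 9.28 and 8.85 ± 5.21 CPM (-1.79 ± 0.52, adjusted p = 0.378). Hcrt, the arousal peptide orexin, was 146 ± 15.7 and 87.0 ± 24.6 CPM (-0.75 ± 0.20, adjusted p = 0.308). Cdkn1a was 6.62 ± 1.18 and 45.6 ± 26.1 CPM (2.79 ± 0.60, adjusted p = 0.285), with 13.3 CPM in mouse 5. Gfap, the filament of astrocytes, was 265 and 160 CPM (-0.73 ± 0.18, adjusted p = 0.285), and Aif1, the microglial protein IBA1, 2.10 and 1.06 CPM (-0.99 ± 0.28, adjusted p = 0.322). The log2 changes of the other genes were -0.62 for Cartpt, 0.48 for Crh, 0.01 for Trh, -0.35 for Pmch, 0.20 for Mc4r, 0.15 for Lepr, -0.27 for Oxt and 0.43 for Avp.

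Of 27 lists, 11 passed camera in hypothalamus, 7 higher and 4 lower. None kept its call with an estimated correlation, where the smallest adjusted p was 0.136, and fry called 1, the endothelial list (adjusted p = 0.00934). Endothelial markers rose (17 tested, all above 0, 6 called over all genes, 13 over the list alone, median 0.88, adjusted p = 3.23e-20, and adjusted p = 0.136 with an estimated correlation). The TGF-beta co-receptor Eng rose from 24.6 to 58.3 CPM (1.25 ± 0.12, adjusted p = 0.00738), the VEGF receptor Flt1 from 84.4 to 196 CPM (1.22 ± 0.14, adjusted p = 0.0136), and Pecam1 from 16.9 to 47.5 CPM (1.49 ± 0.18, adjusted p = 0.0212). The list level was 0.99, 1.08 and 0.98 in oxaliplatin mice 2, 3 and 4 and 0.65 in mouse 5, against -0.02 to 0.01 in vehicle. Glucocorticoid-responsive genes rose (23 tested, all above 0, Lcn2 and Cebpd called over all genes, 22 over the list alone, median 0.72, adjusted p = 4.48e-20, and adjusted p = 0.467 with an estimated correlation). Ddit4, an inhibitor of the growth kinase mTORC1, was 33.9 and 99.9 CPM (1.56 ± 0.29), and the list level in mouse 5 was 0.47, against 1.04 to 1.46 in the other oxaliplatin mice. The p53 targets rose (29 tested, 2 over the list alone, median 0.24, adjusted p = 0.0011, and adjusted p = 0.467 with an estimated correlation), with the death effector Pmaip1 at 1.26 ± 0.30 beside Cdkn1a, and levels of 0.59, 0.39, 0.20 and 0.08 in oxaliplatin mice 2 to 5. Immediate early genes rose (21 tested, 5 over the list alone, median 0.48, adjusted p = 4.22e-05, and adjusted p = 0.467 with an estimated correlation), with Ier3 at 1.20 ± 0.22. Ribosomal protein genes rose (38 tested, all above 0, 0 over the list alone, median 0.25, adjusted p = 3.04e-12, and adjusted p = 0.619 with an estimated correlation), with Rpl4 at 0.31 ± 0.10.

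Cholesterol synthesis genes fell in hypothalamus (24 tested, 22 below 0, 0 over the list alone, median -0.31, adjusted p = 3.56e-10, and adjusted p = 0.467 with an estimated correlation), with Dhcr7, the enzyme of the last step, at 36.2 and 25.7 CPM (-0.50 ± 0.12). Microglia markers fell (18 tested, 17 below 0, 0 over the list alone, median -0.40, adjusted p = 7.28e-08, and adjusted p = 0.467 with an estimated correlation), with the fractalkine receptor Cx3cr1 at 36.1 and 25.2 CPM (-0.52 ± 0.21). These lists and the 5 of the preceding group passed without each of the 7 libraries in turn. Oligodendrocyte and myelin markers fell (16 tested, 0 over the list alone, median -0.34, adjusted p = 0.000912, and adjusted p = 0.676 with an estimated correlation), and lost the call without oxaliplatin mouse 2 (median -0.12, adjusted p = 0.149), whose level was -1.24. The library of that mouse was also high in markers of thalamus, cortex, hippocampus and striatum, given below, and a link was not tested. Inflammatory genes rose (15 tested, 6 over the list alone, median 0.33, adjusted p = 0.00851, and adjusted p = 0.583 with an estimated correlation), with the interleukin 1 receptor Il1r1 called over all genes (1.32 ± 0.19, adjusted p = 0.0400), and lost the call without vehicle mouse 1 (median 0.32, adjusted p = 0.0635) or oxaliplatin mouse 3 (0.09, 0.0690). Cell cycle genes rose (24 tested, 0 over the list alone, median 0.24, adjusted p = 0.0334, and adjusted p = 0.504 with an estimated correlation), with the DNA helicase subunit Mcm7 at 0.38 ± 0.13, and lost the call without vehicle mice 1 (0.26, 0.0723) or 4 (0.31, 0.0777) or oxaliplatin mouse 5 (0.22, 0.129). Erythroid markers fell (9 tested, 0 over the list alone, median -0.14, adjusted p = 0.0404, and adjusted p = 0.676 with an estimated correlation), with levels of -1.32, -1.72 and -0.70 in oxaliplatin mice 2 to 4 and 1.19 in mouse 5 (median -1.94 without it), and lost the call without vehicle mouse 1 (-0.18, 0.0811) or oxaliplatin mice 3 (-0.11, 0.249) or 4 (-0.18, 0.0789).

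The other 16 hypothalamus lists did not pass. Feeding and neuroendocrine peptides and receptors had a median of 0.09 (adjusted p = 0.687), with Npy and Agrp above 0 and Pomc and Hcrt below. Astrocyte markers had a median of -0.13 (0.0817), with 3 members lower over the list alone, Gfap among them. Extracellular matrix genes had a median of -0.20 (0.288), though Col4a1, a collagen of the vessel basement membrane, rose from 34.2 to 87.0 CPM (1.35 ± 0.17, adjusted p = 0.0215). Clock genes had a median of 0.12 (0.475), with 2 members higher and 3 lower over the list alone. Markers of thalamus, cortex, hippocampus and striatum had a median of 0.42 (0.392), with a level of 1.56 in oxaliplatin mouse 2, and choroid plexus and pituitary markers -0.17 (0.288) and -0.29 (0.392). The medians were -0.04 for oligodendrocyte precursors (0.392), 0.12 for the integrated stress response (0.474), -0.03 for the unfolded protein response (0.475), 0.08 for NRF2 targets (0.107), 0.09 for interferon-stimulated genes (0.997), -0.04 for oxidative phosphorylation (0.288) and -0.04 for mitochondrially encoded genes (0.304). Neuronal markers had a median of -0.04 and a mean of 0.0047 (test downward, adjusted p = 0.392), and tanycyte and ependymal markers a median of -0.21 and a mean of 0.08 (test downward, adjusted p = 0.225).

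**Figure D4:**
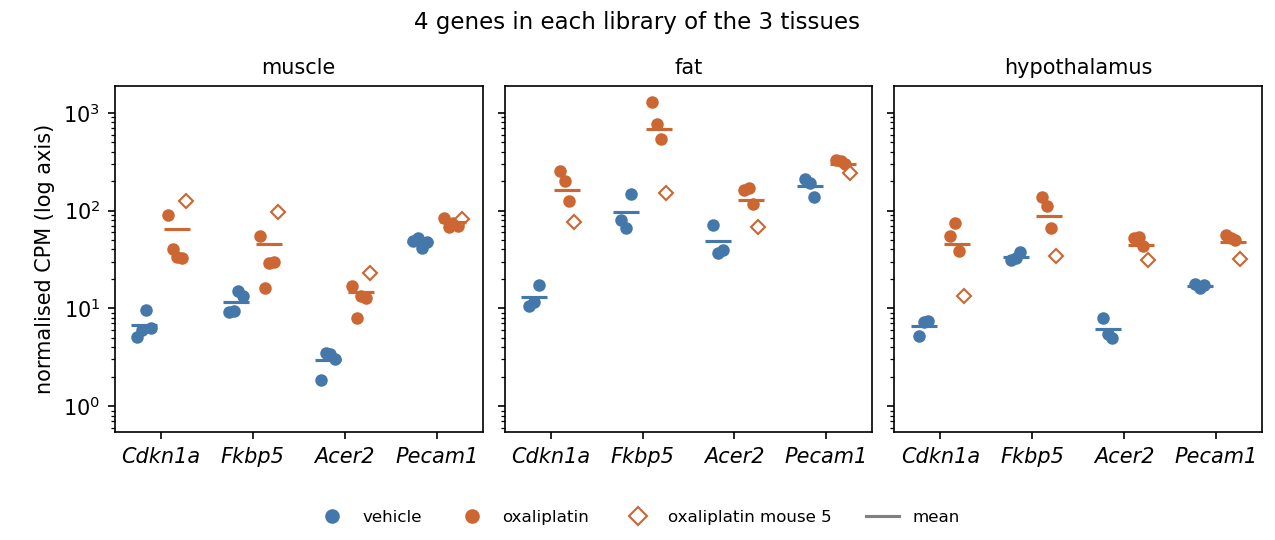
Normalised CPM per library, on a log axis, of Cdkn1a, Fkbp5, Acer2 and Pecam1 in muscle, fat and hypothalamus, with vehicle in blue, oxaliplatin in orange, bars at the group means and an open diamond for oxaliplatin mouse 5. Cdkn1a means were 6.79 and 64.6 CPM in muscle, 13.2 and 164 CPM in fat and 6.62 and 45.6 CPM in hypothalamus for vehicle and oxaliplatin, with no overlap between the arms in any tissue.

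A test of the difference in effect asked which genes responded otherwise in fat than in muscle, the contrast the series sets out. Pfkfb3 rose in muscle (1.67) and was lower in fat (-1.47), a difference of -3.12 ± 0.45 (edgeR adjusted p = 0.0114). Sfrp5 had effects of -2.34 in fat and 0.80 in muscle (difference -3.11 ± 0.39, adjusted p = 0.00544), and Golga7b, a gene of protein palmitoylation, -3.62 in fat and above 0 in muscle (difference -4.60 ± 0.55, adjusted p = 0.00473). The immunoglobulin genes Igha and Iglc2, which were not tested in muscle alone, gave 8.50 ± 1.37 (adjusted p = 0.0252) and 7.58 ± 1.49 (adjusted p = 0.0485). Their effects in fat alone were 4.84 and 3.34, so a part of each difference rests on muscle counts below the count filter. In fat the lymph node and B cell marker level was -1.12 in oxaliplatin mouse 2 and 4.01 in mouse 5. Rgs2, a brake on G protein signals, was 3.85 in fat and -1.11 in muscle (difference 5.00 ± 0.85, adjusted p = 0.0315). The other genes with large differences were Cd300lf, a myeloid receptor (4.28 ± 0.72), the transporter Flvcr2 (3.10 ± 0.61), Togaram2 (-4.55 ± 0.84) and the secreted kinase Fam20c (-3.01 ± 0.50). Cd300lf was below the count filter in muscle, and Togaram2 in fat. In all, 45 of 18862 genes differed, 11 with a higher and 34 with a lower effect in fat. The kits differed between these tissues, and a factor per gene cancels in this contrast while other kit effects do not. Golga7b, Pfkfb3 and Sfrp5 kept their call without any 1 of the 16 libraries. Over all edgeR, DESeq2 and limma-voom settings the highest adjusted p was 0.0200 for Golga7b, 0.0401 for Sfrp5 and 0.116 for Pfkfb3. Pfkfb3 thus lost its call in at least 1 other setting. The named genes with a higher effect in fat, Igha, Iglc2, Rgs2, Cd300lf and Flvcr2, each lost it without fat vehicle mouse 1. They also each lost it without fat oxaliplatin mouse 3 and without fat oxaliplatin mouse 4. The count was 17, 257 and 29 without fat vehicle mice 1, 2 and 4, 14, 15 and 1626 without fat oxaliplatin mice 3, 4 and 5, 22 and 16 without muscle vehicle mice 1 and 3, and 15, 22, 14 and 18 without muscle oxaliplatin mice 2 to 5. It was 13 with muscle mouse 5 set to vehicle.

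The same test between fat and hypothalamus, made with 1 kit, called 65 of 20892 genes, 18 with a higher and 47 with a lower effect in fat. On the lower side were the choline transporter Slc5a7 at -5.73 in fat and 0.31 in hypothalamus (difference -6.05 ± 0.87, adjusted p = 0.0183), the neuronal chromatin subunit Actl6b at a difference of -6.00 ± 0.57 (adjusted p = 0.00652), and Plppr4, a lipid phosphatase-related protein of synapses, at -5.13 ± 0.92 (adjusted p = 0.0398). The transcription factor genes Pou3f4 and Klf14 gave -5.12 ± 0.60 and -5.90 ± 1.12. Actl6b and Pou3f4 had effects of -0.22 and 0.09 in hypothalamus and were below the count filter in fat, so their differences rest on low fat counts. On the higher side, Col11a2, a fibrillar collagen chain, was 2.45 in fat and -1.69 in hypothalamus (difference 4.13 ± 0.60, adjusted p = 0.0183), and Hdc, which makes histamine, 2.86 and -0.24 (difference 3.10 ± 0.56, adjusted p = 0.0398). Sh2d5, the heparan sulfate sulfotransferase Hs3st3b1 and Fam167b gave 3.47 ± 0.46, 3.42 ± 0.60 and 4.22 ± 0.80. Fam167b had an effect of 1.36 in fat and was below the count filter in hypothalamus. The fit takes the libraries of both tissues as separate animals. Limma-voom with the animal as a random effect called 264 genes, at an estimated animal correlation of 0.0667. That setting changes the tool as well as the animal term, so the count does not show what sharing of animals does. In the edgeR fit, Actl6b alone among the 10 named kept its call without any 1 of the 14 libraries. With the mouse number as a block Actl6b lost it too (edgeR adjusted p = 0.0924). The count was 28 without fat vehicle mouse 1, 104, 12, 18 and 3151 without fat oxaliplatin mice 2 to 5, 3, 4 and 6 without hypothalamus vehicle mice 1, 2 and 4, and 41, 24, 13 and 118 without hypothalamus oxaliplatin mice 2 to 5.

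The overlap of muscle and fat asked whether the same genes responded in both. With edgeR calls in 14088 genes tested in both tissues, 0 were shared, since fat had 0 calls, and limma-voom calls also shared 0. At an unadjusted p under 0.01, 41 genes were higher in both tissues against 8.45 by chance (1-sided Fisher's exact test, p = 2.47e-17) and 19 lower in both against 9.48 (exact p = 0.00304), while 18 went opposite ways. The shared higher genes included the p53 targets Cdkn1a, Bax and Trp53inp1, the glucocorticoid-responsive genes Fkbp5 and Errfi1, and the vessel genes Angpt2 and Pecam1, all picked from the 41 after they were seen. With DESeq2 calls, 38 were higher in both against 8.24 (exact p = 7.94e-16) and 10 lower in both against 6.73 (exact p = 0.133). With oxaliplatin mouse 5 left out of both tissues, chosen after seeing the data, 47 were higher in both against 17.7 by chance and 28 lower against 23.6 (exact p = 0.189), and 33 went opposite ways. Genes are not independent of each other, and the animals of the tissues may be shared, so these exact p values describe the gene counts alone.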

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

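The test of a swap of mouse 5 with a vehicle mouse was chosen after the result was seen, while for the test of its label the outcome that would speak for or against it was written down once the pattern was seen and before the test was run.

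Within groups of 4 or 5 libraries, a library far from the others was found in 13 of 235 groups, 5.53%, about the 5% that chance gives, and 5 of the 13 were oxaliplatin mouse 5 in fat or hypothalamus. In fat, mouse 5 stood apart in adipocyte identity genes (-0.22, against -1.87 to -1.61 in the other oxaliplatin mice), cell cycle genes (1.69, against -0.68 to -0.43), Lep (394 CPM, against 5.16 to 11.7) and Scd1 (12993 CPM, against 433 to 938). In hypothalamus, it stood apart in B3gnt3 (1.52 CPM, against 2.67 at the highest). Its genome-wide profile correlated across genes at 0.946 with the vehicle libraries and 0.920 with oxaliplatin mice 2 to 4 in fat, and at 0.988 and 0.977 in hypothalamus, where genes are not independent replicates.

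That mouse 5 received vehicle under a wrong label was argued against by its p53 targets, which lay above the highest vehicle library by more than 1 vehicle SD in 3 of 3 tissues (0.76 against a bound of 0.20 in muscle, 0.51 against 0.13 in fat, 0.08 against 0.059 in hypothalamus, a thin margin). Whether muscle mouse 5 is the same animal is open, and without muscle the p53 argument rests on fat and hypothalamus, mainly on fat. In hypothalamus the endothelial level and Vwf of mouse 5, given above, also lay above all vehicle libraries, whose endothelial SD was 0.015. Those values were picked after they were seen, and Agrp of mouse 5 lay within the vehicle range. A swap with a vehicle mouse sequenced in fat and hypothalamus would put a vehicle library among oxaliplatin mice 2 to 4. Of these tissues, 0 of 6 vehicle libraries correlated better with them than with the other vehicle libraries. Vehicle mouse 3 has no library in these tissues, so a swap with it, or with a mouse not sequenced, could not be seen. A weaker or shorter exposure of oxaliplatin mouse 5, or a milder response, may remain and was not tested. Without mouse 5 edgeR called 4969 genes in fat and 655 in hypothalamus.

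Other single libraries stood apart as follows. Epithelial markers were 0.20 in fat of oxaliplatin mouse 4, against -2.27 to -1.95 in the other oxaliplatin mice. Mitochondrial transcripts were 3.98% of counts in fat of oxaliplatin mouse 2, against 2.75% to 2.93%. Clock genes were 0.28 in hypothalamus of oxaliplatin mouse 2, against -0.05 to -0.0039. In muscle, vehicle mouse 4 had autophagy genes at -0.15, against 0.04 to 0.06, and a depth of 31.2 M, against 27.3 to 27.9 M. Muscle of oxaliplatin mouse 1 had proteasome genes at 0.35, against 0.0023 to 0.08, Gdf15 at 2.0 CPM, against 0.0794 to 0.535, and Ppargc1a at 41.4 CPM, against 50.8 to 53.8.

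By the test of the difference, the oxaliplatin effect (log2) differed between fat and muscle in Igha (8.50), Iglc2 (7.58), Rgs2 (5.00), Cd300lf (4.28), Flvcr2 (3.10), Golga7b (-4.60), Togaram2 (-4.55), Pfkfb3 (-3.12), Sfrp5 (-3.11) and Fam20c (-3.01). It differed between fat and hypothalamus in Fam167b (4.22), Col11a2 (4.13), Sh2d5 (3.47), Hs3st3b1 (3.42), Hdc (3.10), Slc5a7 (-6.05), Actl6b (-6.00), Klf14 (-5.90), Plppr4 (-5.13) and Pou3f4 (-5.12). Of these genes, Igha, Iglc2 and Cd300lf were below the count filter in muscle, Togaram2, Actl6b and Pou3f4 in fat, and Fam167b in hypothalamus.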

How the results depend on the processing

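The counts of called genes depended on the tool, on single libraries and, in muscle, on the label of mouse 5, and the cause was not tested where it is not named. In muscle (24 genes) DESeq2 called 254, limma-voom 13, edgeR without a filter 42, and 1 fit over all tissues 91. With the adipocyte level as a covariate, added after seeing the data, 178 genes were called. With 1 library left out the muscle count ranged from 2 to 17, and with mouse 5 set to vehicle it was 0. In fat (0 genes) DESeq2 called 2450, limma-voom with quality weights 5083 and 1 fit over all tissues 2909. With 1 library left out the fat count ranged from 0 to 4969, without vehicle mouse 4 and oxaliplatin mouse 5 it was 4087, and with the myofibre level as a covariate it was 0, the last 2 settings added after seeing the data. In hypothalamus (28 genes) DESeq2 called 262, limma-voom 11, limma-voom with quality weights 363 and 1 fit over all tissues 55, and with 1 library left out the count ranged from 0 to 655. For the difference between fat and muscle (45 genes) DESeq2 called 804, limma-voom with the animal as a random effect 14, and with mouse 5 set to vehicle 13, and with 1 library left out the count ranged from 14 to 1626. For the difference between fat and hypothalamus (65 genes) DESeq2 called 1273, limma-voom with the animal as a random effect 264 and the filter at 1 CPM 151. With 1 library left out the count ranged from 3 to 3151. The settings with a random effect change the tool as well as the animal term, so their counts cannot be put down to the animal. The overlap of muscle and fat (0 genes) was 48 with DESeq2 calls, 60 at an unadjusted p under 0.01, and 75 at that p without mouse 5 in both tissues, added after seeing the data. DESeq2 kept all 18 named muscle genes and all 15 named hypothalamus genes, and limma-voom kept 9 and 7. The called lists numbered 14 in muscle, 17 in fat and 11 in hypothalamus, and became 0, 0 and 0 with an estimated correlation and 0, 3 and 1 with fry. With 1 library left out they ranged from 10 to 17, from 13 to 19 and from 10 to 13, and with mouse 5 set to vehicle 8 muscle lists were called.

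The direction of the list test turned as follows. With mouse 5 set to vehicle the muscle medians were -0.0629 for glucocorticoid-responsive genes, 0.0084 for denervation genes (test downward) and -0.0491 for Schwann cell markers. With 1 library left out the muscle oxidative phosphorylation median ranged from -0.21 (without vehicle mouse 4, test downward) to 0.14, and the median of the fat list: skeletal myofibre markers from -5.76 to 1.36 (without vehicle mouse 4). Without vehicle mouse 4 and oxaliplatin mouse 5, the fat medians were 1.42 for myofibre markers and -0.86 for cell cycle genes. The median alone also changed sign in called lists. With 1 library left out it ranged from -0.11 to 0.25 in the muscle inflammatory list, whose median changed sign in 6 settings, and from -0.63 to 0.11 in the muscle macrophage list.

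Mouse numbers are shared by the arms, but the libraries of a number did not pair: the correlation of their deviations was over 0.1 in 1 of 4 pairs in muscle, 0 of 2 in fat and 0 of 2 in hypothalamus. The oxaliplatin library of the same number was the best match of the vehicle library in 1 of 4, 0 of 2 and 2 of 2 cases. With the number as a replicate block, 3 genes and 11 lists were called in muscle, 0 and 17 in fat, 37 and 14 in hypothalamus, 362 genes for the difference between fat and muscle, and 47 for that between fat and hypothalamus. In fat and hypothalamus only numbers 2 and 4 occur in both arms, so the blocked effect there rests on 2 libraries per arm. Muscle oxaliplatin mouse 5 likewise adds nothing to it, so these counts do not cover all libraries. Of the 24 muscle and 28 hypothalamus genes called without the replicate block, 2 and 9 were among those called with it, and of the named hypothalamus genes Lrg1, Eng, Flt1, B3gnt3, Tmem252, Clec14a and Il1r1 lost their call. With it 7 of the 10 named genes of the first difference kept their call and 0 of the 10 of the second, Actl6b at an adjusted p of 0.0924, and the fat clock median changed sign, its only change over all settings.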

Other observations

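The tests of whether libraries of the same number come from the same mouse, and the counts of splits at an unadjusted p in muscle and hypothalamus, were chosen after the results were seen, while for the other tests the deciding outcomes were written down before the test was run, though for the 2 weighed patterns after the pattern itself was seen.

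Muscle and hypothalamus shared more raised genes than expected if genes and animals were independent. Acer2 and Pecam1 were called in both tissues, against 0.0289 by chance (1-sided Fisher's exact test, p = 0.000369). At an unadjusted p under 0.01, 32 genes were higher in both against 5.20 by chance (exact p = 1.19e-16), among them the endothelial genes Vwf, Eng, Icam2 and Clec14a, the vessel hormones Adm and Apln, and Lrg1. Fat and hypothalamus shared 39 higher genes against 13.3 (exact p = 1.72e-09), among them Acer2, Cdkn1a, Pecam1 and Slc2a1, and 8 lower genes against 4.99 (exact p = 0.127). All of these names were picked after the genes were seen, and no test of a gene group was made on the shared genes. Genes are not independent of each other, and the animals of the tissues may be shared, so these exact p values describe the gene counts alone.

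The clock repressor Nr1d1 was called higher in muscle (1.37 ± 0.19), while in hypothalamus it was 118 and 85.7 CPM (-0.46 ± 0.14, adjusted p = 0.347) and in fat 353 and 150.3 CPM (-1.23 ± 0.32, adjusted p = 0.118). In muscle Cd74, the invariant chain of antigen presentation, was 120 and 26.4 CPM (-2.18 ± 0.67), which did not pass over all genes.

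The fall of oxidative phosphorylation genes in fat was weighed against myofibres in the vehicle libraries. Vehicle mouse 4 was rich in Ttn (51767 CPM), Acta1 (6686 CPM) and Ckm (5086 CPM), given without TMM factors. With the myofibre level as a covariate the list median was -0.39 (0.5 of the interquartile range 0.0933), against -0.42 without it, and without vehicle mouse 4 it was -0.33. This argues against myofibres as the whole cause. The 16 myofibre genes and the oxidative phosphorylation list share none, though both fibres and adipocytes express the latter. An effect of the drug may remain as a hypothesis, and chance was not excluded for the fat lists.

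The rise of endothelial markers in hypothalamus was weighed against more vessel tissue in the oxaliplatin libraries, which would raise pericyte and smooth muscle genes too. The median of 10 such genes, none of them in another hypothalamus list, was 0.29 with 0.5 of the interquartile range at 0.292, so the values went both ways and more vessel tissue cannot be told apart from higher expression per vessel. Ndufa4l2 was 1.96, Higd1b 1.39, Rgs5 0.59, Vtn 0.54, Pdgfrb 0.30, Tagln 0.29, Myh11 0.16, Acta2 -0.06, Notch3 -0.13 and Anpep -0.56. The depth of the oxaliplatin libraries was lower in hypothalamus, 23.6 to 26.4 M against 27.3 to 28.5 M. An effect of the drug on vessels stays open and untested.

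Whether same-numbered libraries come from the same mouse was tested as a hypothesis, from the correlation across genes of their deviations from the mean of their arm. For fat and hypothalamus the mean correlation was 0.0706, the highest of 144 pairings of the numbers (exact permutation p = 0.00694), which is consistent with shared animals. For fat and muscle it was -0.0841 (exact permutation p = 0.965), and for muscle and hypothalamus -0.0384 (exact permutation p = 0.944), so the muscle numbers may follow another order.

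Other splits of the libraries into groups of the same sizes were counted, the real split included. In muscle 3 of 100 splits called as many genes as the real 24. This share lies under 0.05, but it was the only split count here to do so, and alone it does not exclude chance. The highest other split called 255, with vehicle mice 3 and 4 set with oxaliplatin mice 1, 4 and 5. These were the muscle libraries with the lowest mitochondrial share, 12.2% to 15.6% of counts, against 16.8% to 23.2% in the rest. The split thus follows a structure of the samples, whose cause was not tested. By muscle genes at an unadjusted p under 0.05 in edgeR, 9 of 100 splits gave the real 1414 or more, with a highest other of 2581, so chance was not excluded by that count. For the muscle lists 22 of 100 splits gave 14 or more, with a highest of 19, so chance was not excluded. In fat the real count was 0, so all 35 splits gave as many by necessity, and this count cannot test chance. The split of oxaliplatin mice 2 to 4 from the other libraries called 5282, a structure of the samples. It differs from the real split in mouse 5 alone. By genes at an unadjusted p under 0.05 in edgeR, 2 of 35 splits gave the real 5178 or more, with a highest other of 7980, and for the fat lists 5 of 35 gave 17 or more, with a highest of 18, so chance was not excluded for either. In hypothalamus 2 of 35 splits gave the real 28 genes or more. The other of these, with 1329, set oxaliplatin mice 2 to 4 apart. It too differs from the real split in mouse 5 alone. At an unadjusted p under 0.05 in edgeR, 4 of 35 gave the real 1932 genes or more, with a highest other of 4496. For the hypothalamus lists 18 of 35 gave 11 or more, with a highest of 14, so chance was not excluded by these counts. For the difference between fat and muscle, 4 of 50 splits gave 45 or more (highest other 1517), and between fat and hypothalamus 3 of 50 gave 65 or more (highest other 2976), so chance was not excluded there.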
